A study of Mus musculus with 7 samples.

How the data were processed

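The series holds 7 mouse prostate graft libraries of total RNA, 4 of Pten_KO and 3 of DKO, each with 1 file of read counts per gene. Per the labels' protocols, RNA was extracted with an RNAeasy Plus mini kit and libraries were made with a TruSeq total RNA kit. Per the submitters' processing notes, the tools used were cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2 1.14.1, with the mm10 assembly. The deposited values are whole-number counts per gene, not normalised, and each file lists the same 25006 Ensembl gene identifiers. The annotation release, the strand setting and the counting mode are not given in the sources used here. Counts of overlapping genes and of genes with near-identical copies or processed pseudogenes, such as Psmb9 and Tap1, Hba-a1, Hbb-bs, Eno1, Npm1 and the H2 genes, are therefore uncertain to the extent that the counting divided or dropped shared reads. The same holds for ribosomal protein genes. No mitochondrial gene had a count, so mitochondrial share could not serve as a measure of RNA quality, and Ighm, Igkc and Rn45s were not among the listed genes.

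Names, biotypes and coordinates came from GENCODE mouse release M21, which uses GRCm38, the assembly called mm10. Of the 25006 identifiers 24991 were found there and 15 were not. Groups and replicate numbers were taken from the labels. Total counts ran from 5702380 in Pten_KO replicate 4 to 20001593 in DKO replicate 6, so low counts are least precise in the former. No pair of libraries was identical, and within groups the chi-square statistic over its degrees of freedom was at least 20.2, so no library was counted as a duplicate of another.

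Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 15713, scaled with TMM factors and tested for DKO against Pten_KO with the quasi-likelihood F test on all 7 libraries, without covariates. Benjamini-Hochberg adjustment ran over all genes tested, and genes with an adjusted p under 0.05 were called, with no minimum fold. All tests were two-sided. The common biological coefficient of variation was 0.346. Standard errors are the absolute log2 coefficient divided by the square root of its F statistic. CPM values are counts scaled to the TMM-adjusted library size, and log2 CPM for list means, correlations and principal components used a prior count of 2. Where a gene had no count over a group, a bound was computed against a floor of 3 counts over that group. With 1 to 3 counts, the ratio is given with an exact 95% binomial interval. Bounds and intervals cover counting error only.

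Before the data were examined, 35 gene lists were fixed from general knowledge of the tissue, the genotypes and other cell types that grafts can hold, together with the tests, most alternatives and the rule for named genes. The lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, over the 34 lists with 3 or more genes tested, with Benjamini-Hochberg adjustment over those lists. Per list the members past the gene test were counted over all genes tested and again adjusted over the list alone. None of the calls of these fixed lists held with an estimated correlation. The rule named Trp53, Pten, Bmi1 and Ar; the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, leaving out predicted genes, pseudogenes and antigen receptor segments; and up to 4 members per list with the smallest p in the list's direction, or the 2 most abundant where none passed. Members named outside this rule, such as those that moved against their list or did not pass, were chosen after their values were seen. Further lists described in the closing section were written after the first results were seen, and their p-values were adjusted over those further lists alone.

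The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, robust quasi-likelihood, RLE factors, library totals alone, totals and TMM without the 50 most abundant genes, no low-count filter, a stricter filter of at least 5 CPM in at least 3 libraries, a minimum of 2-fold, each library left out in turn, the replicate number as a block, and for lists camera with an estimated correlation and fry. Added after seeing the data were thinning every library to the smallest total, a correction for GC content and exon length, that correction with the block, and leaving out both libraries numbered 4. The GC and length correction used values for 15702 of the 15713 genes. The labels do not say that replicate numbers 4, 5 and 6, which occur in both groups, mark a shared animal or day.

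The gene test was tested on simulated counts with 200 changed genes, drawn with the real dispersions and library sizes. Both groups took the Pten_KO means. The real comparison called 8415 genes, so the rates below describe a setting with far fewer changes and need not hold there. For DKO against Pten_KO with 15514 genes run, edgeR recovered 0 of 50 genes changed 1.5-fold, 5 of 50 changed 2-fold, 36 of 50 changed 4-fold and 43 of 50 changed 8-fold, with 5 false calls among 89. DESeq2, on 15713 genes, made 55 false calls among 168. A 2-fold change planted in the G2/M and mitosis list was called by camera with the preset correlation, which also called 1 of 33 unchanged lists. Camera with an estimated correlation and fry called the planted list as well, and 0 of the unchanged ones. Simulated genes were drawn independently, whereas the estimated correlation in the data was 0.69 for the G1/S list and 0.8 for the G2/M list. The simulation therefore does not show how the list tests behave with correlated members.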

Results

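RNA was sequenced from mouse prostate grafts that carried Bmi1-CreER, a tamoxifen-inducible Cre recombinase under the Bmi1 locus, together with floxed alleles. In 4 libraries only Pten was floxed (Pten_KO), and in 3 libraries both Pten and Trp53 were floxed (DKO). Pten encodes a lipid phosphatase that opposes PI3K signalling, and Trp53 encodes the tumour suppressor p53. Every sample was labelled as castrated, and the series title places the tumours 5 months after castration. The comparison addresses how castrated tumours deficient in both genes differ in transcript levels from those deficient in Pten alone. Total counts were 5702380, 13432515, 14611282 and 11210318 in Pten_KO replicates 4, 5, 6 and 7, and 17456382, 14215786 and 20001593 in DKO replicates 4, 5 and 6. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical. Levels are in CPM, counts scaled to library size with TMM factors, and are given as mean ± SD with n = 4 for Pten_KO and n = 3 for DKO, and adjusted p-values of single genes come from edgeR's quasi-likelihood test.

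Trp53 was lower in all 3 DKO libraries than in any Pten_KO library. Its level was 44, 34.3, 41.3 and 38.3 CPM in Pten_KO replicates 4 to 7, and 11.3, 20.7 and 14.6 CPM in DKO replicates 4 to 6. The means were 39.5 ± 4.18 and 15.5 ± 4.77 CPM, a log2 fold change of -1.35 (SE 0.22, adjusted p = 0.00268). Trp53 (ENSMUSG00000059552) lies on chromosome 11 from 69580359 to 69591873 of GRCm38, on the plus strand, and is annotated as protein-coding. Pten (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160), which was floxed in both groups, stood at 214 ± 4.84 CPM in Pten_KO and 215 ± 2.02 CPM in DKO, a log2 difference of 0.01 (SE 0.09, adjusted p = 0.936). A count over the whole gene cannot show whether floxed exons were removed, so the Pten counts check neither group's deletion. Bmi1, the gene whose locus drives the recombinase, was at 46.5 ± 2.8 and 53.1 ± 8.81 CPM, a log2 difference of 0.19 (SE 0.14, adjusted p = 0.258), which passed only without DKO replicate 5 (0.34, adjusted p = 0.0407).

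**Figure D1:**
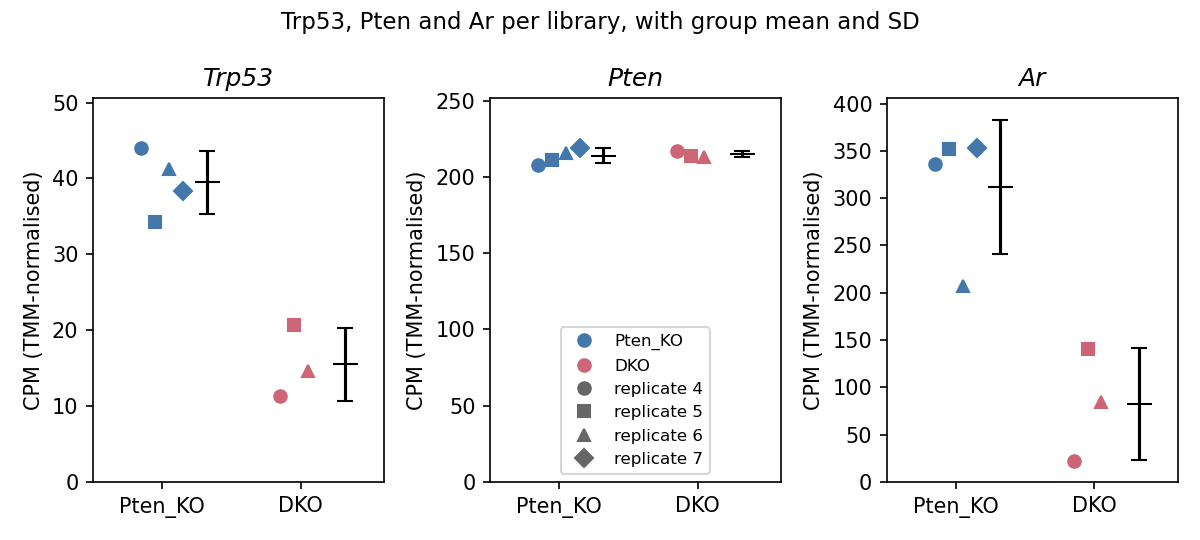
TMM-normalised CPM of Trp53, Pten and Ar (vertical axes, linear from 0) in each library of Pten_KO (blue, n = 4) and DKO (red, n = 3), with the marker shape giving the replicate number and the black bar the group mean ± SD. Trp53 sits between 34.3 and 44 CPM in Pten_KO and between 11.3 and 20.7 CPM in DKO, while Pten lies between 208 and 219 CPM in both groups.

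DKO tumours had more cell cycle, Myc target and collagen transcripts than Pten_KO tumours, and fewer transcripts of MHC class II and T cell genes. The 26 mitotic genes measured were all higher, with a median rise of 10.7-fold, while T and NK cell markers had a median fall of 15-fold. Of 15713 genes tested, 4351 were higher and 4064 lower in DKO at an adjusted p under 0.05, which together is 53.6% of the genes tested. With a change of at least 2-fold required as well, 2296 were higher and 2670 lower. Among the called genes 95.2% had no overlap between the libraries of the groups, as did 58.1% of all genes tested, where chance gives 5.71%. Of the calls, 51.7% were higher in DKO. When library totals alone set the scale, without composition factors, 3180 genes were higher and 5590 lower, so that 36.3% were higher, and the median log2 fold change of all genes shifted by -0.253 relative to the TMM scale. No gene called under both scalings changed direction. The first principal component held 69.2% of the variance and separated the groups, and log2 CPM correlated across genes at 0.707 to 0.875 between groups, 0.915 to 0.98 within Pten_KO and 0.892 to 0.967 within DKO.

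Cell cycle genes rose as a block in DKO. All 22 G1/S and DNA replication genes rose, over all genes tested and also adjusted over the list alone, with a median log2 fold change of 2.39. Mcm5, a subunit of the replicative helicase, went from 13.2 ± 2.37 to 78.6 ± 8.5 CPM (log2 2.56, SE 0.16, adjusted p = 0.000254), and Cdc45, which activates that helicase, from 4.58 ± 1.37 to 50.2 ± 9.09 CPM (log2 3.44, SE 0.25, adjusted p = 0.000258). All 26 G2/M and mitosis genes rose by both adjustments, with a median of 3.42. Ccnb1, which encodes cyclin B1, increased 17.6-fold and Aurkb, a mitotic kinase, 10.7-fold. Of 19 Myc target genes, 18 rose by either adjustment and Fbl did not pass, and the median was 1.26. Npm1, a nucleolar chaperone, rose from 106 ± 6.62 to 343 ± 29.7 CPM, and Srm, the spermidine synthase, from 13.3 ± 2.63 to 90.7 ± 13.1 CPM. Camera with its preset correlation gave adjusted p-values of 1.82e-18 for the G1/S list, 2.43e-20 for the G2/M list and 5.93e-11 for the Myc list. These were adjusted p = 0.352, adjusted p = 0.371 and adjusted p = 0.352 with an estimated correlation. Rrm2 of the G1/S list lost its call without any library except Pten_KO replicate 6 (highest adjusted p = 0.101), and no other member of these lists lost its call without a single library.

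Metabolic lists had smaller medians than the cell cycle lists. In the hypoxia and glycolysis list 11 of 19 genes rose and none fell, by both the adjustment over all genes and that adjusted over the list alone, with a median log2 fold change of 1.21 (camera adjusted p = 3.48e-05, adjusted p = 0.549 with an estimated correlation). Among them were P4ha1 and P4ha2, subunits of the collagen prolyl 4-hydroxylase, at log2 2.8 (SE 0.18) and 2.88 (SE 0.2), and the glycolytic enzyme Eno1 at 2.6 (SE 0.2). P4ha1 and P4ha2 act in collagen synthesis as well as being hypoxia-induced. Of the 21 cholesterol and fatty acid synthesis genes 9 rose and 12 did not pass, the same counts as adjusted over the list alone, with a median of 0.343 (camera adjusted p = 0.0291, adjusted p = 0.779 with an estimated correlation). Sqle, the squalene epoxidase, rose by 1.94 (SE 0.15) and Hmgcr, the rate-limiting reductase of the pathway, by 1.39 (SE 0.13). Without Pten_KO replicate 6 the cholesterol list had a median of 0.268 (adjusted p = 0.0649), and without DKO replicate 5 one of 0.232 (adjusted p = 0.0707). Without Pten_KO replicate 4 it had a median of 0.532 (adjusted p = 0.00861), and with the stricter filter one of 0.232 (adjusted p = 0.0836). With library totals alone its median was 0.0932 (adjusted p = 0.0374). Idi1 lost its call without any library except DKO replicate 6 (highest adjusted p = 0.128), and Slc2a1 of the hypoxia list without any except Pten_KO replicate 4 and DKO replicate 6 (0.083).

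Mesenchymal and matrix genes were higher in DKO. In the epithelial-mesenchymal transition list 15 of 19 genes rose and 4 did not pass, the same counts as adjusted over the list alone, with a median log2 fold change of 1.84 (camera adjusted p = 3.89e-06, adjusted p = 0.456 with an estimated correlation). Fn1, which encodes fibronectin, went from 1260 ± 510 to 9490 ± 734 CPM (log2 2.92, SE 0.36, adjusted p = 0.000928), and the transcription factors Fosl1 and Twist1 rose 21.4-fold and 9.27-fold. In the fibroblast and matrix list 9 of 16 genes rose and 1 fell, the same as adjusted over the list alone, with a median of 1.8 (camera adjusted p = 0.000355, adjusted p = 0.549 with an estimated correlation). Col3a1 went from 1560 ± 809 to 21400 ± 2240 CPM. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) went from 628 ± 370 to 10700 ± 2540 CPM (log2 4.09, SE 0.5, adjusted p = 0.000864). The member that fell was Pi16, a marker of resident adventitial fibroblasts, at log2 -2.28 (SE 0.38, adjusted p = 0.00283). Of the 9 that rose, 5 encode collagens, which mesenchymal cells of several kinds make, and the others were Postn, Fbn1 and the fibroblast markers Fap and Pdgfra, at log2 1.75 (SE 0.28) and 1.88 (SE 0.4). Pdgfrb, Dpt, Mfap5 and Thy1 did not pass, nor did the fibroblast markers Dcn and Lum, at 1190 ± 590 against 652 ± 303 CPM and 312 ± 156 against 362 ± 246 CPM. In the transition list Vim lost its call without Pten_KO replicate 7 or DKO replicate 4 (highest adjusted p = 0.0577), and Prrx1 without Pten_KO replicate 5 or DKO replicate 4 or 6 (0.0814). Snai1 lost its call without any library except Pten_KO replicates 4 and 6 (0.0735).

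Epithelial markers were lower on average in DKO, with 1 library far below the rest. The mean log2 CPM of the luminal epithelial markers was -0.9 in DKO replicate 4, against 6.88 and 5.49 in DKO replicates 5 and 6 and 6.69 to 7.7 in Pten_KO. Cdh1, the epithelial cadherin, stood at 0.835 CPM in DKO replicate 4 and at 418 and 199 CPM in the other DKO libraries, against 753 ± 244 CPM in Pten_KO. No luminal gene passed edgeR's test among 16, nor adjusted over the list alone, and 0 had an unadjusted p under 0.05. DESeq2 called 0 and limma-voom 3 of them lower. The list's median was -1.65 (camera adjusted p = 0.0467, adjusted p = 0.779 with an estimated correlation). Of 16 basal epithelial markers 5 fell, and 4 fell adjusted over the list alone, with a median of -2.03 (camera adjusted p = 0.00529, adjusted p = 0.779 with an estimated correlation). Itgb4, the hemidesmosome integrin, fell from 198 ± 61.8 to 30.5 ± 19.6 CPM, and Jag2, a Notch ligand, from 63.8 ± 13.1 to 16.1 ± 4.08 CPM. The basal mean was 0.63 in DKO replicate 4 and 5.21 to 7.55 in the other libraries. The luminal call was lost without Pten_KO replicate 4 (median -1.45, adjusted p = 0.0918), with library totals alone (adjusted p = 0.179), with the stricter filter (adjusted p = 0.0514) and by fry (adjusted p = 0.153). Fry did not call the basal list either (adjusted p = 0.0517). Of the basal genes that fell, Lama3 lost its call without DKO replicate 6 (adjusted p = 0.0717) and Trp63 without any library except DKO replicates 4 and 5 (highest adjusted p = 0.0965). Without DKO replicate 4 the luminal median was -1.06 (adjusted p = 0.0139) and without DKO replicate 5 it was -2.88 (adjusted p = 0.00622). The basal median was -1.55 (adjusted p = 0.00128) and -2.72 (adjusted p = 0.00169) without these libraries.

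Castration-resistant luminal progenitor markers had no call, with 0 of 16 members past edgeR's test over all genes or adjusted over the list alone. Of these, 1 was lower at an unadjusted p under 0.05, 2 were lower by DESeq2 and 3 by limma-voom, and the median was -1.47 (camera adjusted p = 0.0993). That list was called lower without Pten_KO replicate 5 (median -1.47, adjusted p = 0.0474), DKO replicate 5 (-2.74, adjusted p = 0.0294) or DKO replicate 6 (-1.27, adjusted p = 0.0474), and its median was -0.88 without DKO replicate 4 (adjusted p = 0.147). The 13 squamous differentiation genes tested had 0 members past edgeR's test over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 3 higher, by DESeq2 7 and by limma-voom 0. The list's median of -0.432 and mean of 0.628 differed in sign (camera adjusted p = 0.88). Leaving out DKO replicate 4, where Krt6a was at 0 CPM, turned the squamous list to a median of 2.42 (adjusted p = 0.00311). Its median was also above 0, with no call, without Pten_KO replicate 4 (0.326) or 5 (0.165). Of 18 neuroendocrine markers 7 fell and 3 rose, or 8 and 3 adjusted over the list alone, and the list was not called (median -1.77, camera adjusted p = 0.275). Scg2, a secretory granule protein, fell from 40.3 ± 27.2 to 1.11 ± 0.529 CPM and Celf3, a neuronal splicing factor, from 8.39 ± 2.64 to 1.4 ± 0.321 CPM. The 3 that rose were Stmn2, Ncam1 and Srrm4, at log2 2.95 (SE 0.27), 1.52 (SE 0.19) and 2.32 (SE 0.44). Of those that fell, Ascl1 and Chgb lost their calls without any 1 DKO library (highest adjusted p 0.0807 and 0.0749). Onecut2 lost its call without Pten_KO replicate 7 or DKO replicate 6 (0.0771) and Syp without DKO replicate 4 (0.0525).

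**Figure D2:**
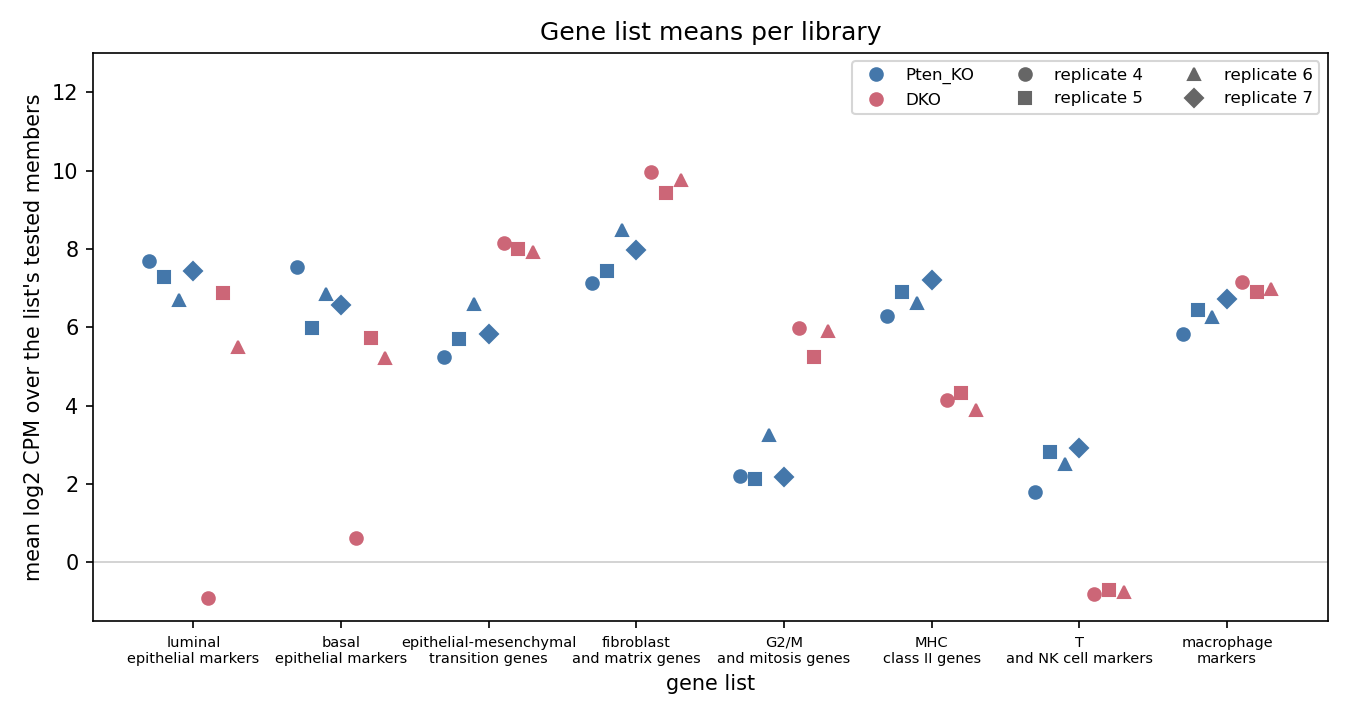
Mean log2 CPM over the tested members of 8 fixed gene lists (vertical axis) in each library of Pten_KO (blue, n = 4) and DKO (red, n = 3), with the marker shape giving the replicate number. DKO replicate 4 lies at -0.9 for the luminal and 0.63 for the basal markers, whereas the 3 DKO libraries lie together for T and NK cell markers, between -0.81 and -0.7, below 1.79 to 2.91 in Pten_KO.

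Ar, which encodes the androgen receptor (ENSMUSG00000046532, chromosome X, 98148769 to 98323215), fell from 312 ± 70.6 to 82.2 ± 59.5 CPM, a log2 fold change of -1.92 (SE 0.58, adjusted p = 0.027). DKO replicate 4, with the lowest epithelial marker levels, also had the lowest Ar level, 21.6 CPM. The Ar call was lost without Pten_KO replicate 5 (-1.86, adjusted p = 0.0573), Pten_KO replicate 7 (-1.87, adjusted p = 0.0576) or DKO replicate 6 (-1.93, adjusted p = 0.0829), and without DKO replicate 5 the log2 fold change was -2.54 (adjusted p = 0.0154). Among 17 androgen receptor and target genes 5 fell and 2 rose, or 4 and 2 adjusted over the list alone, and the list was not called (median -0.32, camera adjusted p = 0.473). Zbtb16 fell from 20.7 ± 3.09 to 2.03 ± 0.473 CPM (log2 -3.34, SE 0.24), while Fkbp5 and Mboat2 rose, at log2 1.71 (SE 0.15) and 1.55 (SE 0.3). The other members that fell lost their calls as well, Abcc4 without DKO replicate 6 (adjusted p = 0.0648) and Herc3 without any library except DKO replicate 5 (highest adjusted p = 0.146). Steap4 lost its call without Pten_KO replicate 4 or 7 or DKO replicate 5 or 6 (0.0771). Prostate secretory proteins were mostly below the filter, with 5 of 13 genes tested, 1 lower and none adjusted over the list alone (median -0.152, camera adjusted p = 0.827). The median was -1.38 without DKO replicate 5 and -0.757 without DKO replicate 6, with no call in either case (adjusted p = 0.545 and 0.494). The lower gene was Bace2, which lost its call without Pten_KO replicate 4 or 7 or DKO replicate 6 (highest adjusted p = 0.0845).

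PI3K and FOXO response genes were lower in DKO. In this list 11 of 17 genes fell and 1 rose, the same as adjusted over the list alone, with a median log2 fold change of -0.948 (camera adjusted p = 0.000645, adjusted p = 0.384 with an estimated correlation). Foxo1, a transcription factor restrained by PI3K signalling, fell from 95.4 ± 15.4 to 25.6 ± 4.02 CPM, and the receptor gene Igf1r from 120 ± 14.8 to 40.9 ± 6.27 CPM. The member that rose was Ccng2, at log2 0.39 (SE 0.1), which was not past the test without Pten_KO replicate 5 or DKO replicate 4 (highest adjusted p = 0.0554). Among those that fell, Erbb3 and Fbxo32 were not past it without Pten_KO replicate 4, 5 or 7 or DKO replicate 6 (highest adjusted p 0.0999 and 0.106). Of 30 p53 target genes 4 fell, 3 rose and 23 did not pass, or 3 and 2 past the test adjusted over the list alone, and the list was not called (median -0.41, camera adjusted p = 0.352). Xpc and Ercc5, which act in nucleotide excision repair, fell by 0.87 (SE 0.18) and 0.76 (SE 0.16) on the log2 scale, and Trp53inp1 fell by 1.57 (SE 0.38). Those that rose were Bax, Apaf1 and Rap2b, at 0.57, 0.38 and 0.79. Apaf1 lost its call when any library except DKO replicate 5 was left out (highest adjusted p = 0.112). The other gene that fell, Mdm2, at -0.55 (adjusted p = 0.0465), lost its call without any library except Pten_KO replicate 5 and DKO replicate 5 (highest adjusted p = 0.156). Cdkn1a, the p21 gene, did not pass, at 47.6 ± 31.2 CPM in Pten_KO and a log2 difference of -0.47 (adjusted p = 0.493).

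Senescence-associated genes were higher in DKO, with 10 of 17 up and none down by both the adjustment over all genes and that adjusted over the list alone (median log2 fold change 1.79, camera adjusted p = 0.00529, adjusted p = 0.352 with an estimated correlation). Timp1, a metalloproteinase inhibitor, rose from 15.6 ± 7.41 to 374 ± 187 CPM and Ccl2, a monocyte chemokine, from 5.49 ± 1.39 to 99.5 ± 44.3 CPM. Both are also secreted by stromal and myeloid cells. With every library thinned to the smallest total the median of this list was 1.1 (adjusted p = 0.00584). Glb1 lost its call without any library except Pten_KO replicates 4 and 5 (highest adjusted p = 0.106). Il6 lost it without Pten_KO replicate 5 or 7 or DKO replicate 4 or 6 (0.0694), and Mmp10 without DKO replicate 4 (0.0512). Nrf2 target genes went both ways, with 5 up and 3 down of 16, or 5 and 5 adjusted over the list alone. Their median was -0.084 while the mean was 0.0804 and camera's direction was up (adjusted p = 0.469). Srxn1, the sulfiredoxin, rose by 1.74 (SE 0.11), and the genes that fell were Pir, Gstm1 and Osgin1, at -0.4, -0.71 and -1.54. Pir lost its call without any 1 library (highest adjusted p = 0.12), Gstm1 without each except Pten_KO replicate 4 and DKO replicate 5 (0.0841), and Osgin1 without each except Pten_KO replicate 6 and DKO replicate 5 (0.148). Without DKO replicate 5 the value of Osgin1 was -2.31. Of those that rose, Nqo1, at 1.04 (adjusted p = 0.0446), lost its call without each except Pten_KO replicates 4 and 6 (0.132). Fry called the Nrf2 list higher (adjusted p = 0.0373) and the JAK-STAT list lower (adjusted p = 0.00305). Of 13 JAK-STAT genes 5 fell and 1 rose by either adjustment, that over all genes and that adjusted over the list alone (median -0.359, camera adjusted p = 0.269). Il6ra, the interleukin 6 receptor, fell by 0.73 (SE 0.11), and Socs3 was the member that rose, at 0.72 (SE 0.2), though not without DKO replicate 4 or 5 (highest adjusted p = 0.0589). Of those that fell, Il6st lost its call without each library except Pten_KO replicate 4 and DKO replicate 6 (0.0853), and Pim1 without each except Pten_KO replicate 6 and DKO replicate 5 (0.139). Stat1 lost its call without DKO replicate 6 (0.0739).

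Antigen presentation and T cell genes were lower in DKO. All 8 MHC class II genes fell by both adjustments, with a median log2 fold change of -2.84 (camera adjusted p = 2.53e-09, adjusted p = 0.352 with an estimated correlation). Ciita (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418), the transactivator of these genes, fell from 83.6 ± 14.6 to 7.45 ± 0.956 CPM (log2 -3.49, SE 0.19, adjusted p = 0.000254), and Cd74, the invariant chain, from 1030 ± 235 to 139 ± 29.9 CPM. Of 12 MHC class I genes 8 fell and 1 rose, or 10 and 1 adjusted over the list alone, with a median of -0.77 (camera adjusted p = 0.0061, adjusted p = 0.549 with an estimated correlation). Nlrc5, the class I transactivator, fell from 196 ± 29.3 to 40.2 ± 4.28 CPM. Calr, a chaperone of the endoplasmic reticulum with many clients besides class I molecules, rose by 1.2 (SE 0.14), and B2m did not pass, at 1430 ± 219 and 1200 ± 184 CPM. The T and NK cell list had 15 of 18 genes lower and none higher, the same as adjusted over the list alone, with a median of -3.91 (camera adjusted p = 1.01e-11, adjusted p = 0.352 with an estimated correlation). Cd3e (ENSMUSG00000032093, chromosome 9, 44998740 to 45009627), a subunit of the T cell receptor complex, fell from 14.6 ± 3.28 to 0.171 ± 0.0199 CPM (log2 -6.34, SE 0.32, adjusted p = 0.000203), and Itk, a T cell kinase, from 19.6 ± 3.39 to 0.442 ± 0.176 CPM. Gzma, Gzmb and Foxp3 did not pass, at log2 -2.08, -0.47 and -0.9, except Gzma without DKO replicate 5 and Foxp3 without Pten_KO replicate 4. Klrd1 lost its call without DKO replicate 4 or 6 (highest adjusted p = 0.0655). In the class I list Erap1 lost its call without DKO replicate 4 (0.0566), Tapbp without DKO replicate 4 or 6 (0.0611) and Psmb8 without Pten_KO replicate 7 or DKO replicate 5 or 6 (0.0852).

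Macrophage markers did not fall with the T cell genes. Of 16, 5 rose and none fell, 1 rose adjusted over the list alone, and the list was not called (median 0.7, camera adjusted p = 0.126). It was called higher without Pten_KO replicate 7 (median 0.845, adjusted p = 0.0302). Msr1, a scavenger receptor, rose from 28.3 ± 12.5 to 111 ± 3.36 CPM. The complement genes C1qa, C1qb and C1qc rose too but lost their calls without Pten_KO replicate 5 or 6 or DKO replicate 4 or 6 (highest adjusted p = 0.102), and Fcgr1 lost its call without any library except Pten_KO replicate 4 (0.103). B and plasma cell markers had 4 of 7 lower by both the adjustment over all genes and that adjusted over the list alone, with a median of -1.99 and no call (camera adjusted p = 0.0576). The B and plasma list was called lower by fry (adjusted p = 0.0146) and without the low-count filter (-2.87, adjusted p = 0.019). It was also called lower without Pten_KO replicate 4 (-2.5, adjusted p = 0.0259), 5 (-2.09, adjusted p = 0.0323), 6 (-2.13, adjusted p = 0.0398) or 7 (-2.34, adjusted p = 0.00669), or DKO replicate 4 (-2.77, adjusted p = 0.0216) or 6 (-3.22, adjusted p = 0.0353). Its member Pou2af1 lost its call without DKO replicate 4 or 6 (highest adjusted p = 0.0791). Neutrophil markers had 1 gene up and 1 down of 10, or 1 and 0 adjusted over the list alone (median -0.186, camera adjusted p = 0.861). Without DKO replicate 5 the neutrophil median was -0.871, with no call (adjusted p = 0.339). The gene that rose was Mmp9, at log2 3.07 (SE 0.41), which other cell types also express, and the gene that fell was Csf3r, at -1.3 (SE 0.39). Csf3r lost its call without Pten_KO replicate 4, 5 or 7 or without DKO replicate 4 or 6, its adjusted p reaching 0.0904. Interferon response genes had 3 up and 3 down of 19 by both the adjustment over all genes and that adjusted over the list alone (median -0.256, camera adjusted p = 0.861). Gbp2 fell by 0.88 (SE 0.13), Ifih1 and Oas2 fell but not without DKO replicate 4 or 6 (highest adjusted p 0.0585 and 0.0658), and Cxcl10, Xaf1 and Bst2 rose, at 1.51, 0.82 and 0.96.

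Markers of other tissue compartments gave 1 call. Of 15 kidney markers only 6 were tested, and the others were below the filter. Of the 6, 4 were up and 1 down by both the adjustment over all genes and that adjusted over the list alone. The kidney list had a median log2 fold change of 2.21 (camera adjusted p = 0.0467, adjusted p = 0.549 with an estimated correlation). Cubn, an endocytic receptor of the proximal tubule, was at 5.21 ± 0.531 and 32.1 ± 15.6 CPM, and Slc12a1, a transporter of the loop of Henle, at 0.134 ± 0.137 and 5.68 ± 2.61 CPM (log2 5.1, or 5.86 without Pten_KO replicate 6). Umod, the uromodulin of the same segment, was at 9.28 ± 9.24 and 0.154 ± 0.267 CPM (log2 -6.02, adjusted p = 0.0271). The Umod call was lost without DKO replicate 4 or 6 (highest adjusted p = 0.0945), and its fitted log2 value ranged from -10.01 to -5.35 as each library was left out. Aqp1, a member that rose, lost its call without Pten_KO replicate 7 or DKO replicate 4 or 6 (highest adjusted p = 0.0786). The kidney call was lost without Pten_KO replicate 4 (median 1.98, adjusted p = 0.115), DKO replicate 4 (2.08, adjusted p = 0.0513) or DKO replicate 6 (2.2, adjusted p = 0.0516), without the 50 most abundant genes (2.25, adjusted p = 0.0523) and without the low-count filter (-0.251, adjusted p = 0.392). Smooth muscle markers had 6 of 11 lower and none higher, or 6 lower and 1 higher adjusted over the list alone, and no call (median -1.86, camera adjusted p = 0.0889). They were called without Pten_KO replicate 4 (-2.07, adjusted p = 0.0137). Myh11, the smooth muscle myosin, fell from 563 ± 283 to 24.2 ± 9.58 CPM, and Des lost its call without DKO replicate 4 or 5 (highest adjusted p = 0.083). Of 12 endothelial markers 4 fell by either adjustment, that over all genes and that adjusted over the list alone (median -1.2, camera adjusted p = 0.14), among them Vwf, from 414 ± 240 to 78.8 ± 30.4 CPM, and the list was called without Pten_KO replicate 4 (-1.46, adjusted p = 0.0201), while its median was -0.585 without Pten_KO replicate 6 (adjusted p = 0.312). Cldn5 of that list lost its call without DKO replicate 4 or 6 (highest adjusted p = 0.0637). Adipocyte markers had 4 of 9 lower, also adjusted over the list alone (median -1.71, camera adjusted p = 0.114), and were called without Pten_KO replicate 6 (-2, adjusted p = 0.000352). Lep and Plin1 lost their calls without any library except Pten_KO replicates 5 and 6 (highest adjusted p 0.0886 and 0.103), and Plin4 without Pten_KO replicate 7 or any 1 DKO library (0.0801). Skeletal muscle markers had 1 of 7 lower by both, also adjusted over the list alone (Atp2a1, median -0.704, camera adjusted p = 0.673). Erythroid genes had 0 of 4 past edgeR's test, also adjusted over the list alone or at an unadjusted p under 0.05, with 0 called by DESeq2 and 1 lower by limma-voom (median -0.251, camera adjusted p = 0.797). The erythroid median was 0.334 without Pten_KO replicate 5 and -1.06 without DKO replicate 5, with no call in either case (adjusted p = 0.979 and 0.352). Immediate early genes had 2 up and 2 down of 13 (median 0.223, camera adjusted p = 0.865), and abundant noncoding RNAs 2 up and 1 down of 8 (median 0.613, camera adjusted p = 0.827), with the same counts adjusted over the list alone. Each called immediate early gene lost its call when single libraries were left out. For Nr4a1 and Zfp36, which fell, this was DKO replicate 6 (adjusted p = 0.0582 and 0.0674). For Egr2 it was Pten_KO replicate 5 or 7 or DKO replicate 4 or 6 (highest adjusted p = 0.0799), and for Ier3 Pten_KO replicate 5, 6 or 7 or DKO replicate 5 (0.0724). The noncoding RNA Rmrp, which rose, lost its call without Pten_KO replicate 5 or DKO replicate 4 (0.0579). Seminal vesicle markers had 1 of 8 genes tested and so no list test; that gene, Pate4, had 1 count over the DKO libraries and 107 over the Pten_KO libraries, a ratio of 103 (95% counting interval 18 to 4090). The DKO count came from DKO replicate 4, and Pten_KO replicate 5 held 63 of the 107 while Pten_KO replicate 4 held none. The Pate4 call was lost without DKO replicate 6 (adjusted p = 0.0594).

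**Figure D3:**
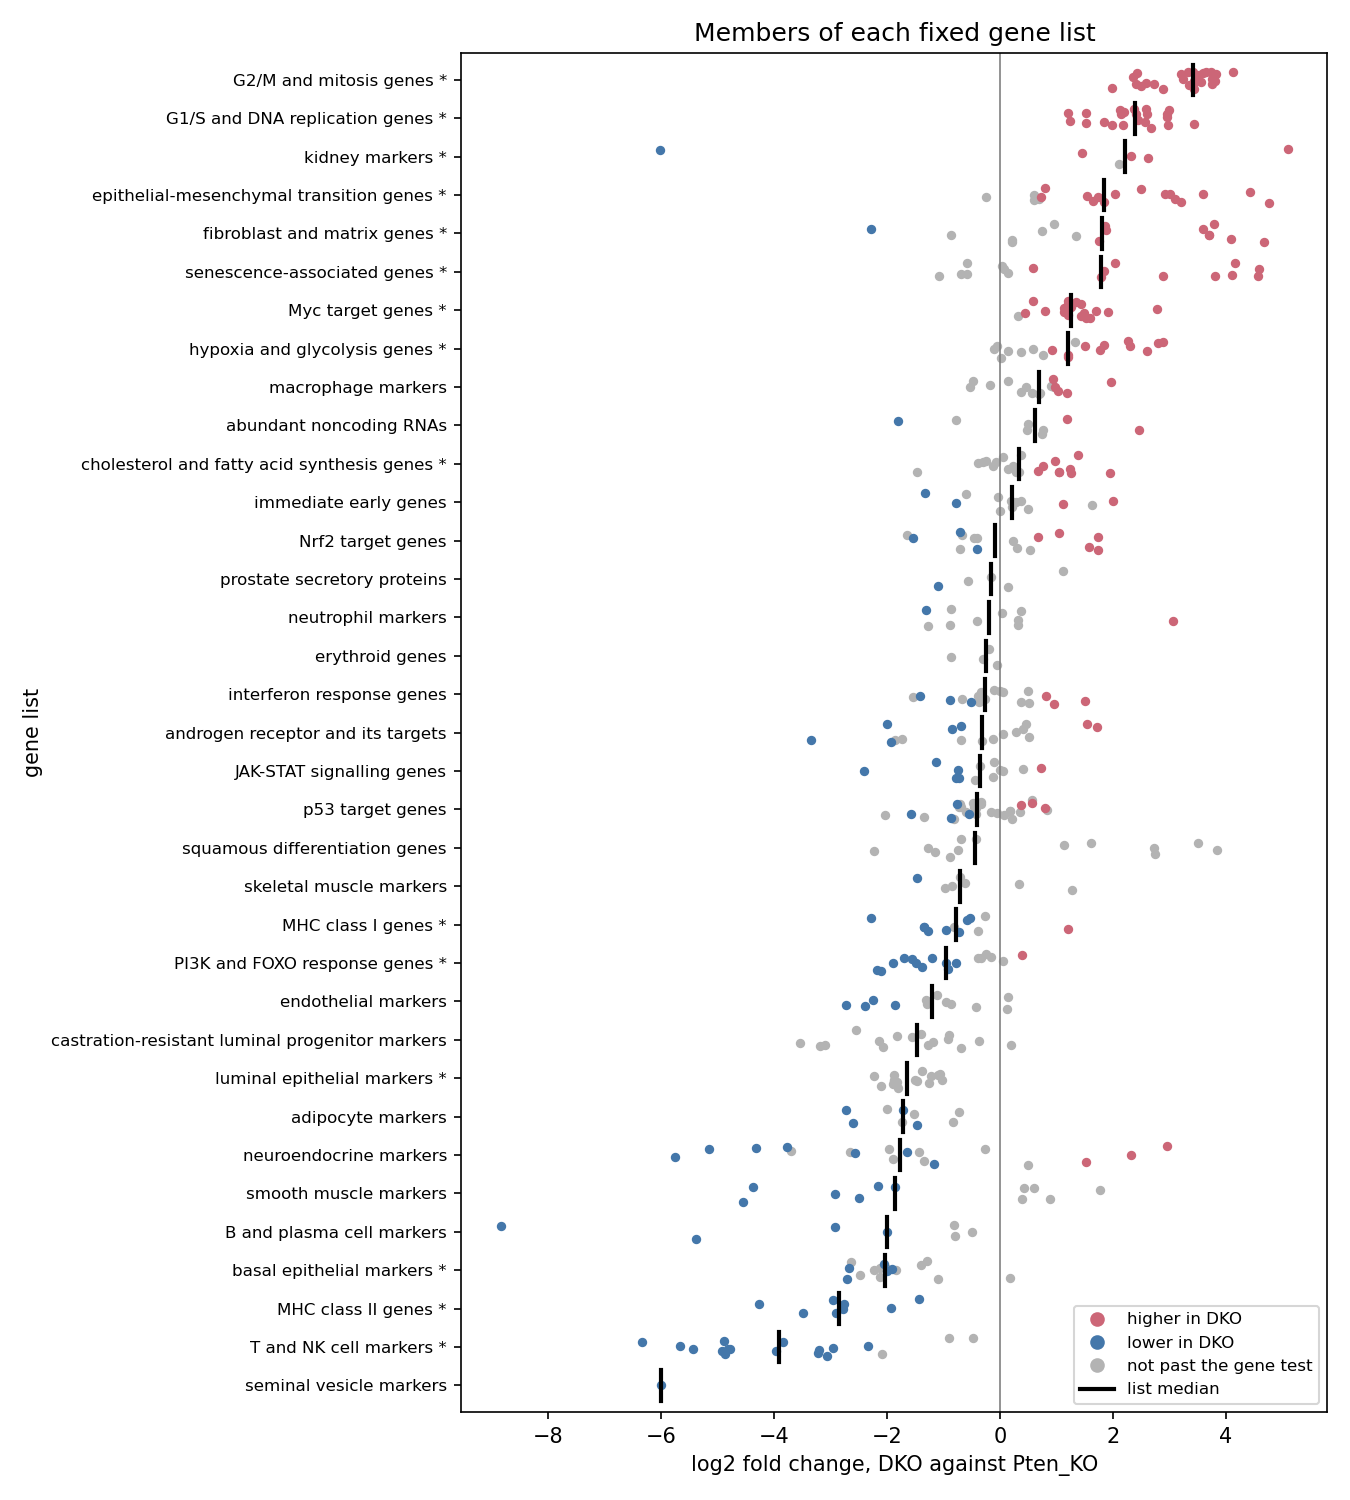
Log2 fold change of DKO against Pten_KO (horizontal axis) for every tested member of the 35 fixed gene lists (vertical axis, ordered by list median), with members higher in DKO in red, lower in blue and not past the gene test in grey, the list median as a black bar and an asterisk on lists called by camera with its preset correlation. All members of the 2 cell cycle lists lie to the right of 0 and all 8 MHC class II members to the left. The list medians run from -6 for the seminal vesicle list, which holds 1 tested gene, to 3.42 for the G2/M and mitosis list.

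In all, 9 of the 34 lists tested were called higher and 6 lower in DKO with camera's preset correlation, and none with an estimated correlation, where the lowest adjusted p was 0.352 and 3 lists had an unadjusted p under 0.05. Fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, called 10 higher and 6 lower. None of the called lists changed direction when RLE factors, library totals alone or totals without the 50 most abundant genes set the scale.

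Of the 10 genes named for the largest rises, Foxg1 (ENSMUSG00000020950, chromosome 12, 49382660 to 49386861), a forebrain transcription factor, had no count in any Pten_KO library and 53.3, 1.23 and 20.4 CPM in DKO replicates 4, 5 and 6, which is at least 423-fold higher in DKO against a floor of 3 counts over the Pten_KO libraries (adjusted p = 0.0182). Without DKO replicate 4 this bound was 201-fold. Without DKO replicate 6 its adjusted p was 0.0567. Chrna1, a subunit of the muscle nicotinic receptor, had 3 counts over Pten_KO and 1615 over DKO, a ratio of 561 (95% counting interval 192 to 2720), and Car6, a secreted carbonic anhydrase, 3 and 459, a ratio of 159 (54.2 to 776). Crabp1, which binds retinoic acid, went from 1.28 ± 1.62 to 244 ± 94.1 CPM, Cthrc1, a secreted protein of collagen-producing cells, from 4.34 ± 2.08 to 326 ± 8.41 CPM, and Hmga2, an oncofetal chromatin protein, from 0.426 ± 0.2 to 30.6 ± 8.2 CPM. Nefm, a neurofilament subunit, Cpne4, Odaph and Stmn4 rose by 6.53 (SE 0.47), 6.84 (SE 0.73), 6.13 (SE 0.98) and 6.01 (SE 0.9) on the log2 scale. Odaph was at 45.2 CPM in DKO replicate 5 against 4.69 and 12.2 CPM in DKO replicates 4 and 6. Without DKO replicate 5 the rise was 4.86 for Odaph and 5.34 for Stmn4, and without Pten_KO replicate 6 it was 6.94 for Odaph. That of Crabp1 went from 7.5 to 8.68 without Pten_KO replicate 7. Of the 3 Pten_KO counts behind the ratio of Chrna1, 2 came from Pten_KO replicate 6, and of the 3 behind that of Car6, 2 came from Pten_KO replicate 4.

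Among the largest falls, Cyp1a1, a target of the aryl hydrocarbon receptor, had no count in DKO and was at 8.82 ± 6.97 CPM in Pten_KO, at least 155-fold lower in DKO against a floor of 3 counts over the DKO libraries. That bound was 91.2-fold without Pten_KO replicate 5, 103-fold without DKO replicate 4 and 94.6-fold without DKO replicate 6. Six3os1 had no count in DKO either and was at least 76.1-fold lower. Pten_KO replicate 4 held 115 of its 238 counts, and the bound was 44.8-fold without that library, 50.7-fold without DKO replicate 4 and 46.6-fold without DKO replicate 6. Six3os1 overlaps Six3 on the other strand, and reads of the pair cannot be told apart where counting does not use strand, which is not given in the sources used here. Themis, a T cell development gene, fell from 20.8 ± 6.59 to 0.138 ± 0.0882 CPM (log2 -7.22, SE 0.49, adjusted p = 0.000258), and Myoc from 49.2 ± 30.9 to 0.38 ± 0.404 CPM (log2 -7.08, or -8.28 without DKO replicate 5). Gcnt3, a mucin glycosyltransferase, had 407 counts over Pten_KO and 3 over DKO, a ratio of 130 (44.2 to 634), and Olfr893 222 and 1, a ratio of 213 (37.9 to 8450). All 3 DKO counts of Gcnt3 came from DKO replicate 6, and the 1 of Olfr893 from DKO replicate 5. Jchain, the joining chain of secreted antibodies, was at 394 CPM in Pten_KO replicate 7 and at 13.4 to 17.8 CPM in the other Pten_KO libraries, against 0.22 ± 0.199 CPM in DKO, and its log2 fold change of -8.83 was -6.04 without that library. Limma-voom did not call Jchain (-7.33, adjusted p = 0.22). Clca1, Alox15 and Itln1, genes of mucous and alternatively activated epithelium or myeloid cells, were highest in Pten_KO replicate 4, at 3630, 490 and 148 CPM, against 78.7 to 428, 13.8 to 58 and 1.29 to 3.53 CPM in the other Pten_KO libraries. Without Pten_KO replicate 4 the log2 fold change of Itln1 went from -7.38 to -3.35, and its call was lost without DKO replicate 4 (-6.79, adjusted p = 0.104), 5 (-8.6, adjusted p = 0.079) or 6 (-7.18, adjusted p = 0.119) and by limma-voom (-4.28, adjusted p = 0.0681). Without Pten_KO replicate 4 that of Alox15 went from -6.96 to -4.83 and that of Clca1 from -7.08 to -4.9. Without DKO replicate 4 or 5 Clca1 was at -6.49 or -7.78. The call of Clca1 was lost without DKO replicate 6 (-7.21, adjusted p = 0.0751).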

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

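The test for a library far from the others was fixed before the data were examined and was applied to the 4 Pten_KO libraries alone. The 3 DKO libraries were not checked, so DKO replicate 4, with its low epithelial marker levels, could not be flagged. The test compares the gap between the most distant library and its nearest neighbour with the range of the group, on the log2 scale. Of 172 values checked, 12 stood out, where chance gives about 8.6. No weighing of explanations was made for these values.

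In Pten_KO replicate 6, Ar was at 207 CPM against 336 to 353 CPM in the other 3 libraries, and Csf3r at 27.7 CPM against 61 to 66.4 CPM. The same library had the highest Cdc45, at 6.63 CPM against 3.8 to 4.03 CPM, Cenpe, at 18.8 CPM against 8.65 to 9.74 CPM, and Col5a1, at 358 CPM against 149 to 170 CPM. Its mean log2 CPM over the G2/M and mitosis genes was 3.26, against 2.13 to 2.21.

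In Pten_KO replicate 4, which had the fewest counts, Syp was at 2.18 CPM against 3.39 to 3.63 CPM, Il6st at 444 CPM against 694 to 735 CPM, and Blk at 2.01 CPM against 5.12 to 5.59 CPM. Tap1 was highest in that library, at 225 CPM against 131 to 143 CPM. In Pten_KO replicate 7, Jchain was at 394 CPM against 13.4 to 17.8 CPM, and the mean log2 CPM of the B and plasma cell markers was 3.11 against 1.65 to 1.72.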

How the results depend on the processing

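Thinning, the GC and length correction, that correction with the block, and leaving out both libraries numbered 4 were chosen after the data were seen. The numbers of genes higher and lower were 4740 and 5000 with DESeq2, 5006 and 5034 with limma-voom, 3700 and 3448 with the stricter filter, 3774 and 3685 after thinning to the smallest library, and 4390 and 4005 with the GC and length correction. Without both libraries numbered 4 they were 4014 and 3513, which held 81.1% of the calls. A minimum of 2-fold left 2296 and 2670. No gene called both by edgeR as reported and in another setting changed direction.

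Replicate numbers 4, 5 and 6 occur in both groups, but same-numbered libraries did not deviate together (r across genes -0.206, -0.0986 and 0.0428), and not every library correlated best with its own number. With the replicate block 2679 genes were higher and 1941 lower, and with the block plus GC and length correction 2544 and 1720; these fits have fewer residual degrees of freedom. Of 137 named genes 103 kept their side of the threshold under the block and 34 were no longer past it. The block also called 4 lists not called without it, namely castration-resistant luminal progenitor markers (median -1.93, adjusted p = 0.0426), B and plasma cell markers (-1.8, adjusted p = 0.016) and endothelial markers (-1.13, adjusted p = 0.0426) as lower and macrophage markers (0.896, adjusted p = 0.0164) as higher.

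Camera with an estimated correlation called 0 lists higher and 0 lower. Leaving out each library in turn gave 3690 to 4478 genes higher, 2723 to 4071 lower, 8 to 10 lists higher and 7 to 8 lower, a Trp53 log2 fold change of -1.59 to -1.15 and a Pten one of 0 to 0.03. The squamous list ranged from -0.748 to 2.42, the latter without DKO replicate 4 (adjusted p = 0.00311); the cause was not tested. Without DKO replicate 6, 24 of 137 named genes were no longer past the threshold, and none reversed in any setting. The smallest library, with 5702380 counts, limits the precision of low counts.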

Other observations

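The ATF4, tRNA synthetase, ribosomal protein, Hox, clock, resident fibroblast, collagen, T cell lineage, NK cell and Y-linked lists, the tests that use them and the look at Xist were chosen after the first results were seen, and the tests of the most abundant genes and of non-tumour cells of every kind after their own results were known. The macrophage, T and NK and transition lists and the count of other splits were planned beforehand. Of 16 targets of ATF4, the transcription factor of the amino acid and stress response, 14 rose, with a median log2 fold change of 1.96 (camera adjusted p = 2.94e-13, adjusted p = 0.0612 with an estimated correlation). Asns, the asparagine synthetase, rose by 3.11 (SE 0.11), and Psat1 and Phgdh, of serine synthesis, by 3.38 and 3.41, while Cebpb and Slc3a2 rose but lost their calls when single libraries were left out (highest adjusted p 0.111 and 0.0575). Of 12 tRNA synthetases described as ATF4-dependent 11 rose (camera adjusted p = 2.42e-10, adjusted p = 0.018 with an estimated correlation), and of 8 other cytosolic ones 6 did (camera adjusted p = 0.00625, adjusted p = 0.081 with an estimated correlation). Their medians were 1.46 and 0.87, a difference of 0.59 (exact permutation p = 0.0173, two-sided, with genes treated as independent). A hypothesis is that ATF4 activity may be higher in DKO beyond a general rise in growth genes. For comparison, 39 of 76 cytosolic ribosomal protein genes rose and none fell, with a median of 0.478 (camera adjusted p = 4.77e-05, adjusted p = 0.22 with an estimated correlation). With library totals alone the median was 0.23, 26 rose and Rps19 fell, at -0.47 (adjusted p = 0.0188). Some ribosomal protein genes, such as Rps6, Rpl19 and Rps16, had very low levels in both groups. Their counts are uncertain where reads shared with near-identical copies were divided or dropped. The list also took in related genes with similar names, such as Rpl3l, Rpl22l1 and Rpl39l. It is therefore a weak gauge of a general rise in growth genes.

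Hox genes, which mark position along the body axis, were mostly lower in DKO. Of 33 tested 19 fell, 2 rose and 12 did not pass, with a median of -1.37 (camera adjusted p = 0.000415, adjusted p = 0.22 with an estimated correlation). Hoxd10 fell from 12.7 to 0.901 CPM and Hoxb6 fell by 2.16 on the log2 scale. Hoxc10 and Hoxa1 rose, at 4.2 and 1.32, and the value of Hoxc10 was 2.89 without DKO replicate 5, which had 12.8 CPM against 0.385 and 4.14 CPM in the other DKO libraries. With library totals alone 21 Hox genes fell and 1 rose. Without DKO replicate 6 both lost their calls, as did 9 of the 19 that fell, namely Hoxa2, Hoxa9, Hoxa10, Hoxa11, Hoxb4, Hoxb8, Hoxb9, Hoxd11 and Hoxd13. Over all single libraries left out the highest adjusted p was 0.0989 for the genes that rose and 0.113 for those 9, and no other called Hox gene lost its call. Clock genes also differed: 7 of 9 genes of the Per and Dbp arm fell (median -1.29, camera adjusted p = 2.91e-05, adjusted p = 0.0612 with an estimated correlation), while in the opposite arm 1 of 5 rose, Nfil3 (median 0.27, camera adjusted p = 0.265). Collection at another time of day could give opposed arms. In the opposite arm only Npas2 was below 0, at -0.17, and only Nfil3 passed the test. The median of 0.27, or 0.02 with library totals alone, lay above the bound of 0 set against the explanation, and below the 0.5 that it needed together with Arntl and Npas2 past the test. Collection time therefore cannot be told apart from other causes.

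The number of changed genes was compared with other groupings of the libraries. Of the 35 splits of the 7 libraries into 4 and 3, only the genotype split, 1 of 35, gave 8415 genes. The highest of the others gave 126. A random labelling of these 7 libraries is thus argued against, though 1 of 35 is the smallest share possible. Every other split puts libraries of both genotypes on the same side, which widens the spread there. The labels do not say that the libraries came from separate animals. A technical difference, or one between single animals, therefore cannot be excluded.

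Matrix and mesenchymal genes were higher in DKO. A larger share of resident fibroblasts would raise resident fibroblast markers along with the collagens. Of 16 such markers Cd34 and Pdgfra rose and 6 fell, with a median of -0.85 (camera adjusted p = 0.047, adjusted p = 0.437 with an estimated correlation). Cd34 and Abca8a lost their calls without DKO replicate 6 among others. Of 9 collagens 8 rose, with a median of 3.6 (camera adjusted p = 8.72e-07, adjusted p = 0.194 with an estimated correlation). The medians differed by 4.45 (exact permutation p = 0.000162, two-sided, with genes treated as independent). Both lists reuse genes whose values were known from the fibroblast and matrix list, such as Pi16 and Col1a1. This difference was therefore partly fixed in advance and cannot decide the question, though the resident markers did not rise as a set. Outside the matrix lists the 50 most abundant genes took 12.2 to 13.3% of the counts in Pten_KO and 10.5 to 11.5% in DKO, a direction that would raise other genes in DKO, whereas with matrix genes counted the shares were 11.3 to 12.9% and 17.7 to 19.1%. The shares outside the lists could shift other genes by at most 0.0459 on the log2 scale, below the transition list's lower quartile of 0.764. These shares alone therefore fall short of the whole rise. This rule was set after earlier forms of the test had given their results, and it leaves out the matrix genes themselves. Library totals alone in place of TMM factors gave a larger median shift over all genes, -0.253, also smaller in size than 0.764. Resident fibroblasts, activated fibroblasts and matrix production by tumour cells stay open, as does the genotype difference itself, which was not tested apart from them.

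T cell genes were lower in DKO, and an equal loss of non-tumour cells of every kind is argued against. The macrophage median lay 4.61 above that of the T and NK list (permutation p = 0.00012, two-sided, 100000 draws, with genes treated as independent). That p-value does not measure the spread between libraries. The comparison was chosen after both medians were known, so the p-value adds nothing to them. What argues against an equal loss is the list means per library. Macrophage means were 6.89 to 7.16 log2 CPM in DKO and 5.82 to 6.71 in Pten_KO. T and NK means were -0.81 to -0.7 in DKO and 1.79 to 2.91 in Pten_KO. Fewer cells of several kinds stays open, since B and plasma, smooth muscle, adipocyte and endothelial markers had medians of -1.99, -1.86, -1.71 and -1.2, with 4, 6, 4 and 4 members lower. With all 7 libraries and the settings used for the report, camera at its preset correlation called none of these 4 lists. It called the B and plasma list lower without the low-count filter (adjusted p = 0.019). With the replicate block it called the B and plasma and endothelial lists lower (adjusted p = 0.016 and 0.0426). Fry called the B and plasma list lower (adjusted p = 0.0146). Hosts that lacked T cells but kept NK cells would lower T cell genes and spare NK cell genes. Hosts that lacked both would lower both. The 13 T cell lineage markers had a median of -4.24 with 12 lower (camera adjusted p = 6.8e-12, adjusted p = 0.0612 with an estimated correlation). The 9 NK markers tested had a median of -1.36 (camera adjusted p = 0.155). The medians differed by 2.88 (exact permutation p = 0.0143, two-sided, with genes treated as independent). The NK members were split, however. Among them 4 fell, Klrb1c, Eomes, Klre1 and Klrc2, at log2 -3.23, -4.94, -3.65 and -5.45. Tyrobp, Klra7, Klra8 and Klra9 did not pass, at 0.63, -1.36, -0.65 and -0.61. Klra4 rose, at 4.24, or 2.83 without DKO replicate 5. The difference in medians therefore does not show that NK cells were spared. Of the NK genes that fell, Klrb1c and Klrc2 were not called without DKO replicate 4 (highest adjusted p 0.0503 and 0.0689). Hosts without T cells therefore stay open, whether or not they kept NK cells. The hosts are not given in the sources used here.

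Xist, which is transcribed from the inactive X chromosome, was at 34.8 ± 20.4 CPM in Pten_KO (n = 4) and 0.876 ± 0.484 CPM in DKO (n = 3), a log2 fold change of -5.27 (SE 0.6, edgeR adjusted p = 0.000713). Female cells in the Pten_KO grafts could give this and would lower Y-linked genes there. The 4 Y-linked genes instead had a median of -0.745 in DKO against Pten_KO, with Kdm5d, Uty and Eif2s3y lower in DKO (camera adjusted p = 0.141). That met the bound set against the explanation, but the bound assumed equal Y-linked transcription per male cell in both groups, and the members spanned 0.954, more than their median, so a minority of female cells cannot be told apart from none. The genotype difference stays open and untested.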
